A study of Sus scrofa and Toxoplasma gondii and Toxoplasma gondii
Sus scrofa with 9 samples.

How the data were processed

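Total RNA was collected with Trizol from 9 samples in 3 groups of 3: uninfected 3D4/21 porcine alveolar macrophages, Toxoplasma gondii Me49 tachyzoites alone, and 3D4/21 cells infected with Me49. Per the labels, libraries were made with the NEBNext Ultra RNA kit and sequenced as paired reads on an Illumina HiSeq. CASAVA 1.8 and TopHat2 2.0.12 are named per the submitters' processing notes. The read counter, the use of strand, the genome builds and the annotations are not given in the sources used here. Without knowledge of strand, reads from a gene and from an antisense or overlapping partner cannot be separated, and reads of near-identical copies may have been split or lost.

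The deposited values are raw read counts per gene, in 1 table aligned to the pig and 1 aligned to the parasite, with 6 libraries in each. Per the labels, reads of the infected samples were aligned to either reference, so these 3 libraries appear in both tables. The pig table holds 30068 features, of which 4746 are unannotated, and the parasite table holds 9198, of which 278 are unannotated. How these features were defined is not given in the sources used here. Samples were grouped by the labels. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

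Pig symbols came from a table of gene IDs, which matched 11804 of the 25322 annotated IDs. The last pig feature on chromosome 1 ends at position 315294641, beyond the last gene on that chromosome in the Sscrofa11.1 name table, at 274280750. The build of the deposited coordinates therefore differs from that table, and coordinates are given only as deposited. The name table holds no Ensembl IDs (0 genes) and added no names. Neither the deposited tables nor the name tables pair parasite IDs with names, and 0 of the 20 parasite lists fixed before the data were examined could be tested. Parasite genes are therefore given by ID, limited to 2 that rose and 2 that fell, a choice made after the lack of names was seen.

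Genes were tested with edgeR 4.0.16 in R 4.3.3, by the two-sided quasi-likelihood test with TMM scaling, after filterByExpr with its minimum count of 10 and a prior count of 0.125. P-values were adjusted by the Benjamini-Hochberg method within each table, and a gene is said to have risen or fallen, or to be called, at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the test statistic. CPM values use the TMM-scaled totals of the tested genes, and their mean and SD are over 3 libraries. Fold changes are model estimates.

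Of 26 pig gene lists fixed before the data were examined, the 23 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry. A list's adjusted p is from camera at the preset correlation unless said otherwise, adjusted over the 23 lists. The genes named in the text follow a rule fixed beforehand. It takes the 8 largest increases and 8 largest decreases among called genes with a symbol, separate groups and a mean over 6 libraries of at least 10 CPM. From each list it takes the 2 called members with the smallest adjusted p in the majority direction and 1 in the other direction. This gave 64 pig genes, of which 1 is not reported here. Any other gene was chosen after its values were seen, and is named as such.

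The procedure was tested on simulated data in which 200 genes were changed by known folds. In the pig comparison, with 17375 simulated genes tested, edgeR recovered 17.9% of 1.5-fold, 55.2% of 2-fold and 86.4% of 4-fold changes, and 11 of 117 calls were false. In the parasite comparison, with 8029 genes tested, it recovered 65.7%, 86.6% and 98.5%, and 14 of 181 calls were false. The false share was above the nominal one in both. The 200 changed genes are a far smaller share than the 20.2% (pig) and 67.1% (parasite) called in the real data. The adjusted p depends on that share, so recovery in the real data may differ.

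Replicates were compared before averaging by a chi-square test over features with a summed count of at least 20. The smallest chi-square per degree of freedom between any pair was 5.35, so no 2 libraries agree within sampling noise. Alternatives, listed before the data were examined, were DESeq2 1.42.0, limma-voom, RLE or library-size scaling, no filter or a filter of at least 10 CPM in 3 samples, a stricter adjusted p of 0.01, removal of the 100 most abundant genes, thinning to the shallowest sample, the replicate number as a block, and leaving out each replicate in turn. The removal of the mitochondrial features was added after the data were seen. Counting intervals are exact at 95% and cover counting error only, since the reads carry no molecular identifiers. Tables were handled with Python 3.11.15 and pandas 2.3.3.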

Results

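Cells labelled as porcine alveolar macrophages and the protozoan parasite Toxoplasma gondii were profiled together by RNA sequencing to follow both transcriptomes during infection. The host cells were 3D4/21, an immortalised line derived from pig alveolar macrophages. The parasite was strain Me49, used as tachyzoites, its fast-dividing stage. There were 9 libraries in 3 groups of 3: uninfected cells, parasites alone, and infected cells. Infected cells had received 5 parasites per cell for 1 h, were washed, and were cultured for 15 h more. The labels give about 36 h of culture for the uninfected cells and about 48 h in HFF cells, a human fibroblast line in which the parasite is grown, for the parasites alone. Host cell and culture time thus differ between the parasite groups, and the stated culture time differs between the pig groups, although the labels describe the controls as kept under like conditions.

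Pig counts totalled 19175987, 19481181 and 16897555 in uninfected replicates 1, 2 and 3, and 20638506, 20900642 and 24402835 in infected replicates 1, 2 and 3. Parasite counts totalled 14570462, 13884149 and 13883390 in the parasites alone, against 9075081, 6105298 and 5944133 in the infected samples. Parasite reads made up 30.5%, 22.6% and 19.6% of the assigned reads of infected replicates 1, 2 and 3, with a mean of 24.2% ± 5.66 (SD, n = 3).

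The uninfected cultures expressed several epithelial and matrix markers at high levels and most macrophage markers at low levels. KRT8, a keratin, stood at 1231 ± 157 CPM, CLDN4, a tight junction protein, at 498 ± 13.3 CPM, and the adhesion proteins EPCAM and CDH1 at 403 ± 27.5 and 245 ± 42.7 CPM (SD, n = 3). The macrophage markers CD14 and LAPTM5 stood at 10.6 ± 0.827 and 26.5 ± 4.16 CPM, and SPI1, a transcription factor of myeloid cells, at 3.95 ± 1.39 CPM. PTPRC, the pan-leukocyte antigen, and TYROBP, a myeloid adaptor, had 0 counts in these 3 libraries, but a count of 0 can also come from the gene model, since TPI1, a glycolytic enzyme that cells in general use, had 0 CPM in all 6. Among markers in the table, 7 of 12 epithelial, 3 of 23 macrophage, 16 of 34 matrix and fibroblast and 2 of 8 endothelial genes reached 10 CPM, with the matrix protein FN1 at 11652 ± 1073 CPM and the endothelial receptor FLT1 at 39.9 ± 18.0 CPM. The median uninfected mean was 0.234 CPM over the macrophage and 57.3 CPM over the epithelial markers in the table. EPCAM, CDH1, KRT8, LAPTM5, SPI1, PTPRC, TYROBP, TPI1, FN1 and FLT1 were chosen after their values were seen.

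**Figure D1:**
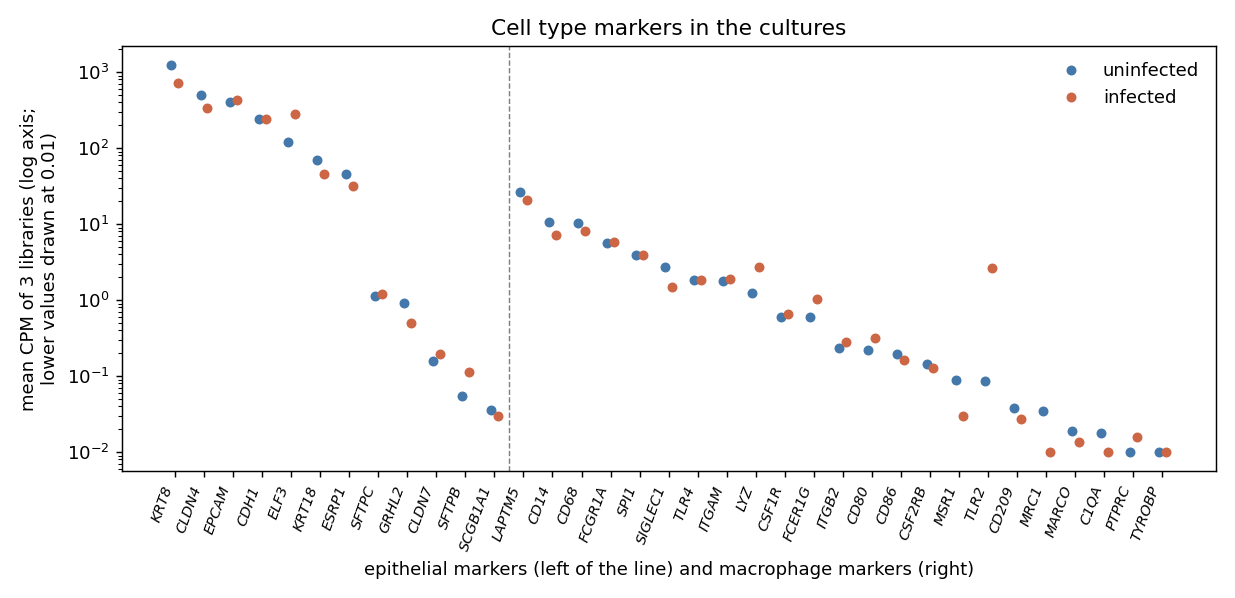
Mean CPM of 3 libraries (log axis) for epithelial markers, left of the dashed line, and macrophage markers, right of it, in uninfected (blue) and infected (red) cultures; values under 0.01 are drawn at 0.01. In uninfected cells KRT8 stands at 1231 CPM and CD14 at 10.6 CPM.

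The first comparison asks how the pig cells' transcriptome differs after infection. The largest increases among genes with a symbol and a mean over 6 libraries of at least 10 CPM included IL19, IL20 and CXCL2. IL19, a cytokine of the IL-10 family, rose from 1.75 ± 1.44 to 558 ± 46.5 CPM (SD, n = 3), a 320.4-fold increase (log2 fold change 8.32, SE 0.45, edgeR adjusted p = 5.32e-05). Its relative IL20, next to it on chromosome 9 (73855726 to 73859626), rose 212-fold. The neutrophil chemokine gene CXCL2 rose 50.8-fold, complement C3 32.3-fold, and PTGS2, the inducible cyclooxygenase, 16.8-fold to 841 ± 242 CPM. The largest decreases among such genes were smaller: TGFBI, a matrix protein, fell 3.59-fold and SMTN, a protein of actin filaments, 3.34-fold.

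In all, 3552 of 17562 tested genes (20.2%) differed by edgeR's test, 1932 higher and 1620 lower in infected cells. At least 2-fold changes numbered 593 higher and 407 lower, and at least 8-fold changes 72 higher and 4 lower. The first principal component held 55.9% of the variance and separated the groups. Groups did not overlap for 39.99% of all tested genes, where chance gives 10%. The number of calls fell to 2267, 1948 and 2190 without uninfected replicate 2, infected replicate 2 or infected replicate 3, and to 1345 at an adjusted p of 0.01. Without infected replicate 1, the genes called lower fell to 1052. With library-size scaling alone the split turned to 1725 higher and 1874 lower, so which direction held more calls depends on the scaling.

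The other large increases among these genes were of ALOX15B, a lipoxygenase, 192-fold from 0.107 ± 0.00522 to 21.8 ± 15.5 CPM, of RHCG, an ammonia transporter, 76.2-fold, and of DUOX2, a hydrogen peroxide-producing oxidase, 28.1-fold. ALOX15B had 2 counts in each uninfected library, so its small SD there does not show the counting error. IL20 had 2, 9 and 2 counts in uninfected replicates 1, 2 and 3. The folds of ALOX15B and IL20 are therefore uncertain. Beside TGFBI and SMTN, those that fell most among called genes with a symbol, separate groups and a mean over 6 libraries of at least 10 CPM were RACGAP1, needed for cytokinesis, by 3.31-fold, TMEM45B by 3.28-fold, SEMA6A, a semaphorin, by 3.21-fold, PCDH1, a protocadherin, by 3.06-fold, TPM1, a tropomyosin, by 3.05-fold, and NES, the intermediate filament nestin, by 3.03-fold. Over the alternatives the log2 fold change ranged from 7.83 to 9.06 for IL19, 7.39 to 8.76 for IL20, 6.89 to 7.98 for ALOX15B, 4.48 to 5.77 for C3 and 4.25 to 5.94 for DUOX2. Several of these genes varied among uninfected libraries. C3 stood at 25.4 ± 21.9 CPM there, from 2.72 in replicate 1 to 46.4 in replicate 3. DUOX2 stood at 0.983 ± 1.02 CPM, from 0.0534 in replicate 1 to 2.08 in replicate 3, and IL19 also varied. TGFBI and TPM1 stood at 198 ± 73.3 and 139 ± 50.5 CPM. The deposited CXCL2 model spans 74206843 to 74311988 on chromosome 8, so its counts may hold reads of neighbouring CXC chemokine genes.

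**Figure D2:**
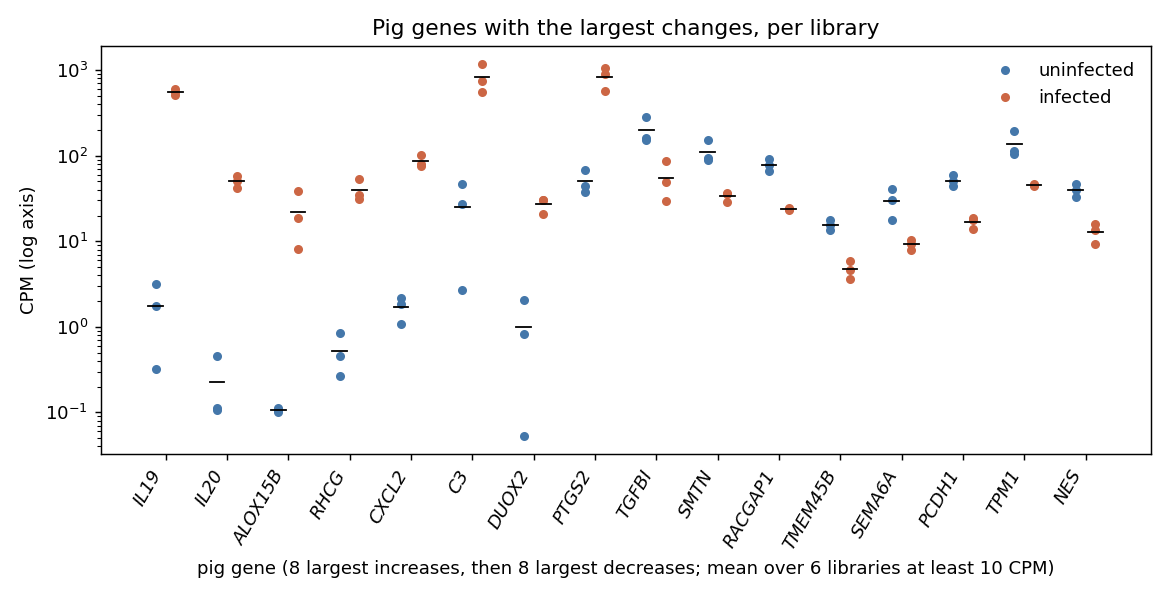
CPM (log axis) of the 8 pig genes with the largest increases and the 8 with the largest decreases among called genes with a symbol, separate groups and a mean over 6 libraries of at least 10 CPM; each point is 1 library, blue uninfected and red infected, and bars are means of 3. IL19 stands at 558 CPM in infected and 1.75 CPM in uninfected cells.

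Genes of inflammation rose together. Of 19 tested cytokines, chemokines and NF-kB targets, 14 rose and 0 fell, also when adjusted over the list alone (14 and 0), with a median log2 fold change of 1.48 (camera adjusted p = 8.43e-38). This was the 1 list that was also called with an estimated correlation (adjusted p = 0.0123). NFKBIA, the inhibitor that NF-kB induces, rose 11.8-fold, from 34.7 ± 6.21 to 409.6 ± 30.2 CPM. Chosen after their values were seen, CXCL8 rose to 10.4 ± 5.14 CPM, CCL5 from 13.3 ± 2.65 to 137 ± 18.5 CPM, TNFAIP3 to 245 ± 24.4 CPM (log2 fold change 3.29) and IL1A from 65.0 ± 13.2 to 421 ± 163 CPM.

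Immediate early and MAPK feedback genes rose in 10 of 16 cases with 0 lower (adjusted over the list alone, 11 and 0; camera adjusted p = 1.45e-10, adjusted p = 0.1 with an estimated correlation). ATF3, a stress-induced transcription factor, rose 2.80-fold and JUNB, an AP-1 subunit, 2.86-fold. STAT3 and STAT6 targets rose in 4 of 10 cases with 0 lower (6 and 0 adjusted over the list alone; adjusted p = 2.73e-06, adjusted p = 0.0993 with an estimated correlation). They included JUNB again and BCL3, a nuclear NF-kB cofactor, which rose 4.12-fold.

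The interferon-stimulated genes were divided. Of 31 tested, 10 rose, 1 fell and 20 were not called, with 12 higher and 2 lower adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.37 with an estimated correlation). MX1, an antiviral GTPase, rose 3.35-fold to 93.2 ± 29.8 CPM. CXCL11, a T cell chemokine, had 2 counts in all uninfected libraries and 101 in the infected ones, a ratio of 42.5 with a counting interval of 11.5 to 356. STAT2, which carries the interferon signal, fell 1.54-fold. OAS2, an antiviral synthetase chosen after its values were seen, stood at 61.7 ± 4.12 and 63.1 ± 5.56 CPM in uninfected and infected cells and was not called. Of 8 antigen presentation genes, 3 rose and 0 fell (the same adjusted over the list alone), including the peptide trimming enzyme ERAP1, 1.82-fold, and TAPBP, tapasin, 1.81-fold. The list was not called (camera adjusted p = 0.0651), but it was without uninfected replicate 3 (adjusted p = 0.0259).

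Sterol and fatty acid synthesis genes were also higher. In cholesterol biosynthesis 13 of 20 genes rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 1.52e-07, adjusted p = 0.37 with an estimated correlation). LSS, an enzyme of the pathway, rose 1.76-fold, from 337 ± 15.9 to 593 ± 64.7 CPM. In fatty acid synthesis and desaturation 7 of 13 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 6.75e-05, adjusted p = 0.208 with an estimated correlation). FASN, fatty acid synthase, rose 2.38-fold to 2157 ± 167 CPM and FADS1, a desaturase, 2.31-fold, while ACSL3, an acyl-CoA synthetase, fell 1.39-fold.

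Stress and redox lists held changes in both directions. In the integrated stress and unfolded protein response 5 of 20 genes rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.017, adjusted p = 0.503 with an estimated correlation). PSAT1, of serine synthesis, rose 2.43-fold and SLC3A2, an amino acid transporter chain, 2.22-fold, while VLDLR fell 1.33-fold. The call was lost with limma-voom (adjusted p = 0.113) and without uninfected replicate 3 (adjusted p = 0.109). Among antioxidant genes 6 of 16 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.00646, adjusted p = 0.419 with an estimated correlation). GSR, glutathione reductase, rose 1.74-fold and TALDO1, transaldolase, 1.52-fold, while CAT, catalase, fell 1.49-fold.

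Mitotic genes were lower. Of 24 G2/M genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 6.75e-05, adjusted p = 0.503 with an estimated correlation). KIF23, a kinesin of the midzone, fell 1.79-fold and HMMR 1.71-fold. Of 19 G1/S and replication genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0651). E2F8, a repressor of E2F targets, fell 2.67-fold and MCM5, a helicase subunit, 1.30-fold, while CDT1, a licensing factor, rose 1.49-fold. Without uninfected replicate 3 or infected replicate 1 the G1/S list was called lower (adjusted p = 0.00308 and 0.0225). Mitochondrially encoded genes rose in 3 of 13 cases with 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.0126, adjusted p = 0.577 with an estimated correlation), among them ND5, 1.42-fold, and ND4, 1.32-fold. That call was lost without uninfected replicate 3 or infected replicate 1 (adjusted p = 0.0804 and 0.0551). In infected replicate 3, 2 unnamed features of the mitochondrial genome stood at 367 and 4844 CPM, 31.4-fold and 39.1-fold the mean of the other infected libraries.

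The remaining lists were not called. Of 16 p53 targets, 4 rose and 0 fell (5 and 4 adjusted over the list alone; adjusted p = 0.0651), including FAS, a death receptor, 11.5-fold, and PMAIP1, a pro-apoptotic gene, 3.29-fold. The p53 list was called without uninfected replicate 1 or infected replicate 1 (adjusted p = 0.0251 and 0.0114). Of 16 apoptosis regulators, 4 fell, the same adjusted over the list alone (adjusted p = 0.225), including TNFRSF1A, 1.25-fold, and XIAP, 1.29-fold. Of 17 glycolysis genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.221): HK2, hexokinase, rose by 0.84 on the log2 scale and PKM, pyruvate kinase, fell 1.26-fold. BNIP3L, a mitophagy receptor, fell by 0.59 on the log2 scale, the 1 called HIF target of 16, also adjusted over the list alone (adjusted p = 0.378). NDUFA6, 1.51-fold higher, was the 1 called gene of 29 for oxidative phosphorylation, also adjusted over the list alone (adjusted p = 0.858), where the median log2 fold change was -0.01 and the mean 0.02. Of 14 chaperones 2 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.601): HSPE1 rose 1.67-fold, HSPA1L 1.73-fold, with reads that near-identical HSP70 genes may share, and HSPA4L fell 1.40-fold. Of 34 autophagy and lysosome genes 4 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.162), with NPC1, a cholesterol exporter, 2.35-fold higher, and CTSB, a cathepsin, and GABARAPL2 lower by 1.56-fold and 1.38-fold. RPS27L, 1.28-fold lower, was the 1 called ribosomal gene of 27, and 0 were called adjusted over the list alone (adjusted p = 0.203). With a replicate left out, calls were lost for PKM, TNFRSF1A, XIAP, RPS27L, BNIP3L, NDUFA6 and GABARAPL2 here, and for MCM5, CDT1, ND4 and ND5 above, with a largest adjusted p over the alternatives of 0.137 for PKM, 0.126 for TNFRSF1A, 0.129 for XIAP and 0.159 for RPS27L.

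No list of cell type markers was called, while some of their genes changed. Of 22 matrix and TGF-beta response genes, 5 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.0651), among them TGFBI and SPARC, the latter 2.24-fold, and the list was called without uninfected replicate 2 or infected replicate 1 (adjusted p = 0.0137 and 0.00697). Of 9 epithelial markers, 3 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.173): CLDN4 by 1.48-fold, ESRP1, a splicing regulator, by 1.44-fold and KRT8 to 716 ± 131 CPM, while ELF3, an epithelial transcription factor, rose 2.32-fold. Of 11 macrophage markers, TLR2 rose from 0.0874 ± 0.0811 to 2.62 ± 1.04 CPM (log2 fold change 4.78, 4.26 to 5.45 over the alternatives) and CD14 fell 1.48-fold, both also called adjusted over the list alone (list adjusted p = 0.822). The call of CD14 was lost with any 1 replicate left out (largest adjusted p 0.0969). The macrophage list had a median log2 fold change of -0.01 and a mean of 0.42. Endothelial markers had 4 tested members, neutrophil and erythroid markers 2 and lymphocyte markers 0, too few to test. By fry, which asks whether a list's genes moved on balance in 1 direction, 11 of the 23 lists were called. They were 8 of the 10 lists called by camera, without G2/M (fry adjusted p = 0.111) and mitochondrially encoded genes (0.0916), and 3 that camera did not call: p53 targets (higher, 0.0236), autophagy (lower, 0.00969) and epithelial markers (lower, 0.028).

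**Figure D3:**
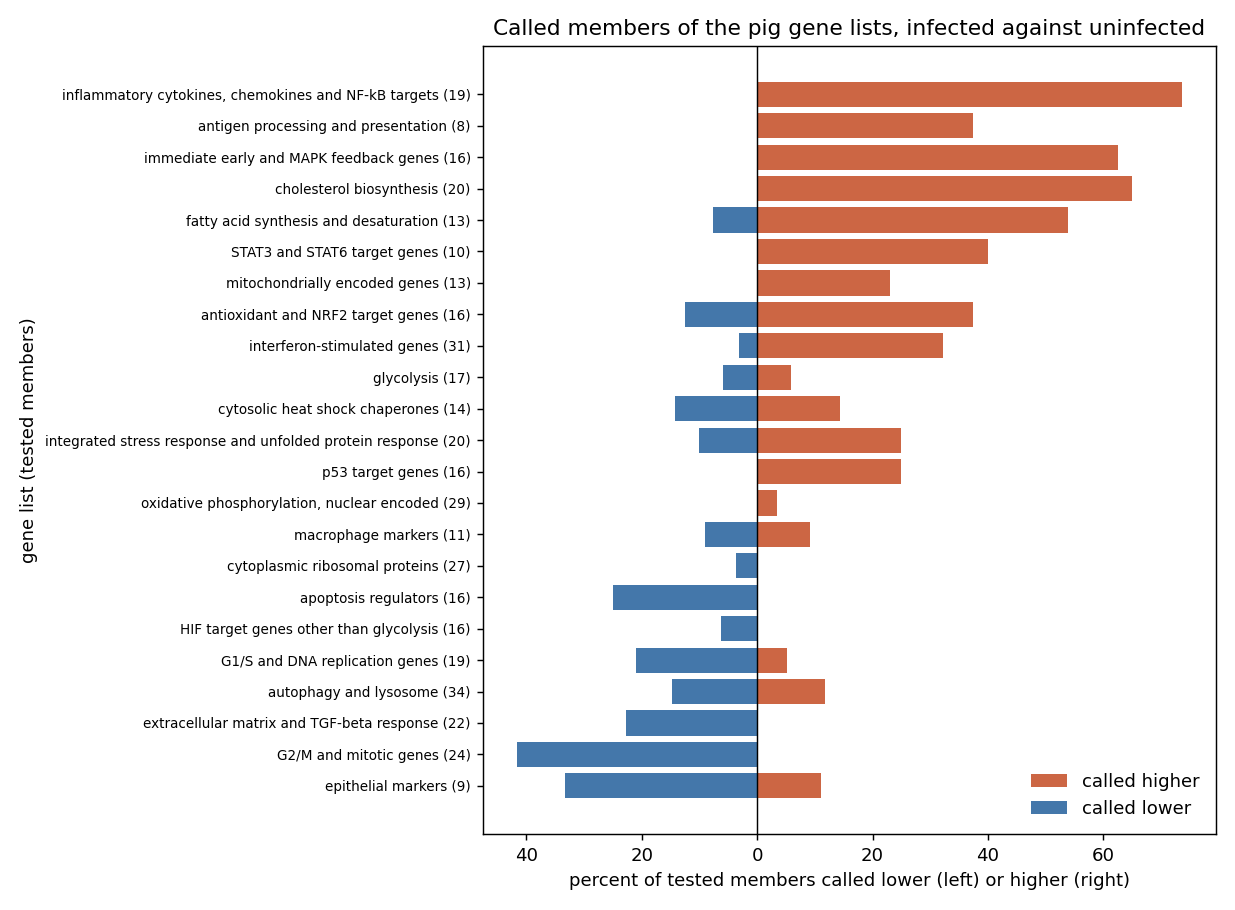
Percent of tested members of each of the 23 pig gene lists called higher (red, right) or lower (blue, left) in infected against uninfected cells by edgeR; the number tested is in parentheses. Of the inflammatory list 14 of 19 rose, and of the G2/M list 10 of 24 fell.

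The second comparison asks how the parasite's transcriptome inside the pig cells differs from that of parasites alone. Parasite genes cannot be named here, since the tables used pair no ID with a name. The gene TGME49_214545 rose from 3.05 ± 0.439 to 26.2 ± 2.80 CPM (SD, n = 3), an 8.57-fold increase (log2 fold change 3.10, SE 0.19, edgeR adjusted p = 6.26e-07), and TGME49_272290 rose 7.92-fold. The gene TGME49_245980 fell from 248 ± 48.6 to 16.8 ± 2.06 CPM, 14.8-fold lower (log2 fold change -3.89, SE 0.17, adjusted p = 4.57e-07), and TGME49_270260 fell 13.1-fold. These are the largest changes among called genes with an annotated ID, separate groups and a mean over 6 libraries of at least 10 CPM.

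Of 8076 tested parasite genes, 5415 (67.1%) differed, 2723 higher and 2692 lower in the infected pig cells. At least 2-fold changes numbered 884 higher and 1049 lower, and at least 8-fold changes 4 higher and 66 lower. The first principal component held 84.3% of the variance and separated the groups. The 10 most abundant genes took 8.22% ± 0.882 of counts in the parasites alone and 5.40% ± 0.253 in the infected samples, and the 100 most abundant took 22.9% ± 1.78 and 17.5% ± 0.652 (SD, n = 3). With library-size scaling alone the median log2 fold change of tested genes moved from -0.01 to 0.14 and the split to 3213 higher and 2115 lower, so directions of small changes hold relative to the TMM scale. The parasite libraries from infected cells were the shallower ones, and HFF host, time in culture and the pig cell environment differ together between these groups.

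**Figure D4:**
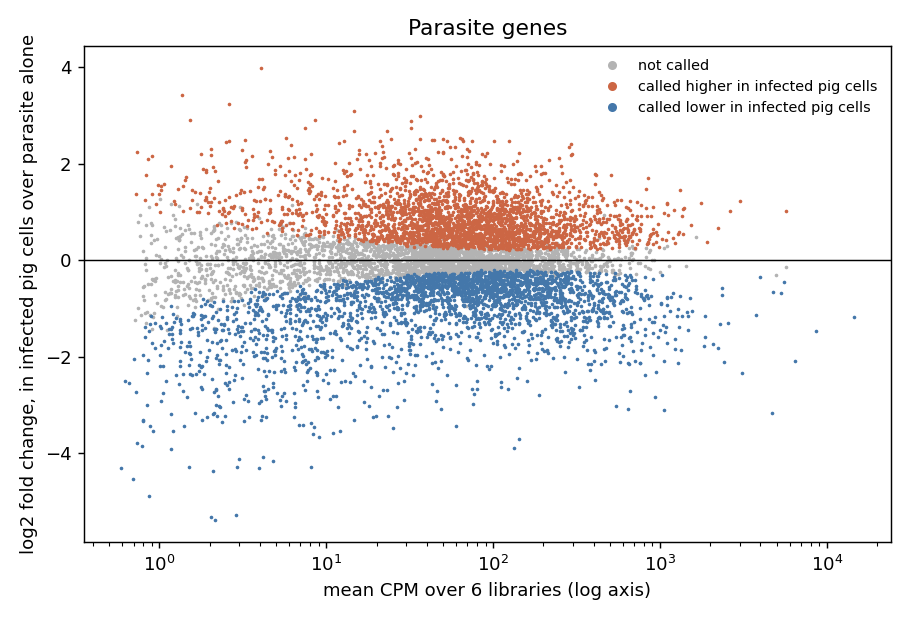
Log2 fold change (in infected pig cells over parasite alone) against mean CPM over 6 libraries (log axis) for 8076 parasite genes; red genes were called higher, blue lower and grey not called by edgeR. Similar numbers lie on each side, 2723 higher and 2692 lower.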

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

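The mitochondrial removal was chosen after the data were seen; the other settings were fixed beforehand. No called gene changed sign among those called in both fits, in any setting of either table. Of the 64 named pig genes, 48 kept their call in every setting that tested them, and all 4 parasite genes did; 72 of 1076 pig gene results lost the call. Pig calls numbered 1345 at an adjusted p of 0.01 (851 higher, 494 lower, 580 at least 2-fold), and at least 2-fold calls 401 at 10 CPM in 3 samples, where fewer genes were tested. Leaving out 1 replicate gave 1948 to 3227 calls, 1202 to 1792 higher and 746 to 1435 lower, with fewer samples. Removing the mitochondrial features gave 3602 calls. Parasite counts stayed within 1.5 times in every setting (4403 to 5464 calls), and the mean parasite share was 21.1% to 26.6% with an infected replicate left out.

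Pig lists called numbered 10, and 1 with an estimated correlation, which ended the call of the interferon (adjusted p = 0.37), STAT3 and STAT6 (0.0993), immediate early (0.1), cholesterol (0.37), fatty acid (0.208), mitochondrially encoded (0.577), G2/M (0.503), stress response (0.503) and antioxidant lists (0.419). The inflammatory list was called in all 18 alternatives (largest adjusted p 0.0123), with a median log2 fold change of 1.45 to 2.58. The stress response list was lost with limma-voom (0.113), and it (0.017) and the mitochondrially encoded list (0.0126) missed 0.01. The G1/S list was called with library-size scaling (0.0464) and without the filter (0.0422). With a replicate left out, adjusted p ranged from 0.0259 to 0.257 for antigen presentation, 0.0436 to 0.635 for ribosomal proteins, 0.00697 to 0.465 for the matrix, 0.00308 to 0.465 for G1/S, 0.00561 to 0.109 for the stress response, 0.00312 to 0.0804 for mitochondrially encoded genes and 0.0114 to 0.115 for p53 targets. The cause was not tested. Without the 100 most abundant genes, or without mitochondrial features, the mitochondrially encoded list had too few members to test.

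Whether the replicate numbers pair the samples could not be told. In the pig table same-numbered deviations correlated at 0.22, 0.10 and 0.15, which leaves a pairing possible. The others ran from -0.26 to 0.15. Deviations were taken from each group's mean, so higher same-number values lower the others. The mostly negative sign of the others is therefore no separate evidence. Uninfected replicate 3 correlated about equally with infected replicate 2 (0.152) and infected replicate 3 (0.148). In the parasite table same-numbered deviations correlated at 0.11, 0.04 and -0.09, so a pairing was not seen there. With the replicate block, 4373 pig and 5294 parasite genes were called, and the p53 (adjusted p = 0.0375) and matrix (0.0274) lists became called. In simulated pig data 17.9% of 1.5-fold changes were recovered; thinning to the shallowest sample gave 3455 calls.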

Other observations

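The tests of the mitochondrial protein genes, the fibroblast genes, the parasite reads and the other splits were chosen only after the result was seen, as were the genes in this paragraph. The maturation factors of DUOX2 rose with it: DUOXA1 went from 0.0732 ± 0.0865 to 4.52 ± 0.694 CPM (SD, n = 3, log2 fold change 5.87, edgeR adjusted p = 0.000388) and DUOXA2 from 0.179 ± 0.155 to 4.82 ± 0.841 CPM (4.71, adjusted p = 0.0011). Uninfected values near 0 make these folds uncertain: over the alternatives the log2 fold change ranged from 5.32 to 7.14 for DUOXA1 and from 4.14 to 5.17 for DUOXA2. The chloride channel CFTR rose from 32.8 ± 4.82 to 111 ± 7.29 CPM, the anion exchanger SLC26A6 from 26.8 ± 4.22 to 109 ± 6.82 CPM, the connexin GJA1 from 128 ± 17.7 to 444 ± 79.6 CPM and the transcription factor EGR1 from 45.0 ± 15.6 to 219 ± 25.3 CPM. These genes were picked by size of change, so they are not evidence of a shared programme. The identity of the cultures, labelled as macrophages, is in doubt, since 3 of 23 macrophage and 7 of 12 epithelial markers reached 10 CPM in uninfected cells. So did 16 of 34 matrix and fibroblast and 2 of 8 endothelial markers. But COL1A2, COL3A1, DCN, LUM, BGN and FBN1 stood at most at 0.354 CPM there, and KDR, TEK, ERG and ROBO4 at most at 0.0937 CPM. The matrix and endothelial counts therefore do not by themselves point to fibroblasts or endothelial cells. Of these low genes, DCN, LUM and ERG had 0 counts there, which can also come from the gene model. The 0 counts of PTPRC and TYROBP weigh little in the doubt, since TPI1, which cells in general use, also had 0 CPM. PTPRC did have 1 count over the infected libraries. The doubt rests on the macrophage markers as a set, with a median uninfected mean of 0.234 CPM.

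Both gene comparisons can be set against the other splits of their 6 samples, but 10 splits are too few for a share under 0.05. With edgeR the real split gave 3552 pig calls and the other splits at most 0, and for the parasite 5415 and at most 0. In each, 1 of 10 splits reached the real count. Every other split has both groups on both sides, so the difference between the groups adds to the spread within each side. With a difference this large such mixed splits could hardly give calls, so their 0 calls do not measure chance. For the lists, the real split gave 10 calls, while other splits gave up to 13, and 3 of the 10 splits, the real one included, gave at least as many. The mixed splits still hold part of the infection difference, so their counts of lists are not a chance level either. The number of lists called at the preset correlation therefore cannot be judged from these splits. The inflammatory list alone was called with an estimated correlation.

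In infected replicate 3, 2 unnamed mitochondrial features were far above the other infected libraries, 31.4-fold at positions 1246 to 2205 (8901 counts) and 39.1-fold at positions 2274 to 3844 (117385 counts). A rise of all mitochondrial transcripts is argued against, since the 13 mitochondrial protein genes had a median log2 difference of -0.18 (SD 0.13) in that library. RNA that poly(A) selection normally removes might have reached the library. Of 235 short features, of at most 150 bases, 1 was at least 4-fold above both other infected libraries there. The count was 0 in either other infected library, too few to decide. The 2 mitochondrial features are 960 and 1571 bases long, so a test on such short features could also miss RNA of their length. The 3 tested histone genes had a median log2 difference of -0.18, but no prediction named this comparison. Whether the transcripts of these genes lack poly(A) was not checked, so they do not decide it. Of all tested features, 13 were at least 4-fold above both other infected libraries in infected replicate 3. In infected replicates 1 and 2 there were 9 and 8. The cause stays open.

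The rise of the pig inflammatory genes was weighed against foreign reads, since the parasites came from human cells. Human fibroblast RNA was looked for in COL1A2, COL3A1, DCN, LUM, BGN and FBN1, abundant in fibroblasts. The highest infected mean was 0.531 CPM. But DCN and LUM had 0 counts in both groups, which can come from the gene model. Whether human reads align to these pig models was not checked, so the low values cannot decide on such RNA as the cause. Traces of it may be present, since total counts of FBN1 went from 13 to 35 and of COL3A1 from 1 to 6. Among other matrix genes, picked after their values were seen, MMP1 went from 9 to 35 and PDGFRB from 10 to 29. Parasite reads aligned to pig genes are argued against, because the 14 called genes had a median log2 difference of -0.11 (SD 0.53) between infected replicates 1 and 3, where the parasite to pig totals differed by 0.85. A response to infection stays a hypothesis; material carried over with the parasites and the different culture times are untested and may contribute.

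Called parasite genes tended to change in the same direction as their neighbours. Among 3633 neighbouring called pairs, 64.3% went the same way, where permuting directions within chromosomes gave 48.6% to 51.8% (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Reads shared by adjoining gene models are argued against as the whole cause, since 1024 pairs at least 2000 bases apart still agreed in 57.0%, against 47.1% to 53.2%. The share among 309 overlapping pairs was 63.4%, near that of all pairs. This cannot decide on shared reads, since the read counter is not known and all pairs include the distant ones. With the lower share among distant pairs, a part played by shared reads stays open. Local base composition or shared regulation could also contribute and were not tested, and genes are not independent replicates.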
